A study of Mus musculus with 40 samples.

How the data were processed

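The submitters deposited 1 gene table and 1 piRNA-locus table per library. Total RNA of testicular cells was enriched for mRNA with poly-dT beads, fragmented and copied into cDNA by random priming, per the labels' protocols. Trimmomatic, STAR and RSEM were named in the submitters' processing notes, with the builds GRCm38 and mm10, and their versions were not given in the sources used here. The deposited expected counts are RSEM's estimated reads per gene or per piRNA locus, not scaled to library size, per the file headers. The deposited TPM values are scaled by the authors' RSEM run to a fixed sum per library, per the file headers. Neither the labels nor the file headers state whether counting used strand, so values of antisense genes and of overlapping genes are uncertain, as are those of near-identical copies such as Zfy1 and Zfy2, Ccdc7a and Ccdc7b, or the Rhox genes, whose reads the counting could have split.

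Gene identifiers were matched to GENCODE M21, on GRCm38. Of 55401 genes, 55141 matched, and the 260 others held 0.009% of the counts. The 214 piRNA loci carry the suffixes PPBD (50 loci), PPBI (65 loci) and PrePP (99 loci), which the labels and file headers do not define. The suffixes are used here only as names of classes.

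Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled with TMM, and each age was fitted on its own 8 libraries with the robust quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. CPM, the usual scaling of counts to library size, uses the TMM-scaled library sizes. Each log2 fold change is Setx-KO over WT, and its SE is the absolute log2 fold change divided by the square root of F. The difference of the Setx-KO effect among ages was an interaction term in a fit of all 40 libraries, and WT development was a fit of the 20 WT libraries. The piRNA loci used the library sizes and TMM factors of the gene table. X-linked genes and the 22 gene lists (500 genes) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, two-sided, and again with an estimated correlation. The list tests were adjusted together over all lists and ages. Other tests used DESeq2 1.42.0, limma-voom and limma-trend on log2(TPM + 1). Groups of piRNA classes were compared with a two-sided exact permutation test of 4 against 4 values, whose smallest p is 0.0286. The p-values measure the spread between libraries, and only the file names tie a library to an animal.

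The gene lists, the comparisons and the alternatives were fixed before the data were examined, except for 4 alternatives, chosen after seeing the data, that leave the library labelled WT replicate 2 at 16 dpp out of a WT change or of the shared WT fit. The lists are spermatogonia, meiotic entry, meiotic recombination, synaptonemal complex and cohesin axis, pachytene and diplotene spermatocyte, round spermatid, piRNA pathway, DNA damage response of sex chromosome silencing, X-linked genes expressed before silencing, Y-linked genes, autosomal retrogene copies of X-linked genes, R-loop and transcription termination factors, p53 targets, interferon response, replication-dependent histones, Sertoli cell, Leydig cell, peritubular myoid cell, endothelial cell, macrophage and leukocyte, red blood cell, and epididymis. The genes named per age are Setx, the 8 largest rises and the 8 largest falls in log2 fold change among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1, no overlap between the 4 Setx-KO and the 4 WT values and a proper gene symbol, and up to 4 members of each list with the smallest adjusted p. For the difference among ages, the 8 genes with the smallest p are named. For WT development, members of the lists are named, up to 4 per list by smallest adjusted p. Up to 5 piRNA loci in each direction are named per age by smallest p. Not all genes that the rule takes are named.

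Replicate numbers 1 to 4 occur in both genotypes. At 12 dpp the deviations of same-numbered WT and Setx-KO libraries from their group means correlated across 11115 genes with r = 0.404, 0.197, 0.372 and 0.231 for numbers 1 to 4. At 14 dpp the values across 11256 genes were 0.66, 0.557, 0.654 and 0.337. All 8 lie above 0.1, so the libraries were treated as paired by number at these ages. No label explains this. At 12 dpp, though, the correlation was 0.274 within replicates 1 and 2 and within 3 and 4, and −0.251 between them. Pairs and these 2 sets cannot be told apart at 12 dpp. WT replicate 4 correlated best with KO replicate 3 there and with KO replicate 1 at 14 dpp. The fit with the replicate number as a block is given beside a count or list of 12 or 14 dpp where it changes a call or moves the count by more than 1.5 times, and beside a named gene where it ends a call. The sequencing index sequences in the file names repeat between replicates 1 and 3 and between replicates 2 and 4 in all 10 groups, so replicates 1 and 2 were taken as one pool and replicates 3 and 4 as another, and values within each pool are given.

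On simulated counts with 200 changed genes, the 4-fold changes were recovered at 92.4%, 95.5%, 83.3%, 89.4% and 92.4% for 10, 12, 14, 16 and 18 dpp. The 1.5-fold changes were recovered at 79.1% and 73.1% at 10 and 12 dpp, and at 17.9%, 8.96% and 13.4% at 14, 16 and 18 dpp. False calls made up 3.54% to 7.49% of all calls of genes. The simulation drew each gene on its own, without stage, pair or pool variation shared across genes. Real rates can therefore differ. In the simulated test of the difference among ages, 77.3% of the 4-fold changes were recovered. Of 4-fold changes at 40 simulated piRNA loci per age, 97.5%, 97.5%, 85%, 87.5% and 100% were recovered at the same ages, and false calls made up 2.5%, 11.4%, 0%, 2.78% and 9.09% of the calls.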

Results

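RNA-seq of testicular cells was compared between Setx-KO and WT mice at 10, 12, 14, 16 and 18 days postpartum (dpp), the ages at which the first wave of germ cells passes through meiotic prophase. Setx encodes senataxin, a helicase that acts on RNA:DNA hybrids. The series asks what loss of Setx does to gene expression during this wave. It holds 40 libraries, 4 per genotype and age, with 9219910 to 14949514 expected counts per library over genes. The 10 most abundant genes took 3.32% to 5.07% of the counts, and mitochondrial genes 1.25% to 3.68%. A table of the same libraries counts 214 piRNA loci, with 99879 to 388546 expected counts per library. Values are group means ± SD with n = 4 per group unless another n is given, and adjusted p-values of single genes and piRNA loci are from edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment.

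Setx (ENSMUSG00000043535, chromosome 2, 29124181 to 29182471 on GRCm38) rose with age in WT and stayed lower in Setx-KO. In WT replicates 1 to 4 its level was 193, 270, 296 and 303 CPM at 10 dpp, 353, 496, 581 and 565 at 12 dpp, 1990, 1030, 831 and 1600 at 14 dpp, 2690, 1000, 2250 and 2260 at 16 dpp, and 3170, 3420, 2310 and 1880 at 18 dpp. In Setx-KO replicates 1 to 4 it was 135.59, 139.12, 142.95 and 140.87 CPM at 10 dpp, 376, 340, 359 and 400 at 12 dpp, 557, 408, 346 and 561 at 14 dpp, 805, 513, 542 and 541 at 16 dpp, and 876, 834, 848 and 657 at 18 dpp. The Setx-KO mean was 52.6%, 73.9%, 34.3%, 29.2% and 29.8% of the WT mean at the 5 ages in order. The log2 fold change was −1.54 (SE 0.29, adjusted p = 0.0377) at 14 dpp, −1.77 (SE 0.3, adjusted p = 0.0257) at 16 dpp and −1.74 (SE 0.2, adjusted p = 9.75e-05) at 18 dpp. At 10 dpp it was −0.93 (SE 0.13) with all 4 Setx-KO values under all 4 WT values, and the adjusted p was 0.0776. At 12 dpp it was −0.44 (SE 0.16, adjusted p = 1). The library labelled WT replicate 1 at 12 dpp, at 353 CPM, lies inside the Setx-KO range of 340 to 400. The library labelled WT replicate 2 at 16 dpp, at 1000 CPM, lies nearer to the Setx-KO maximum of 805 than to the other WT libraries, and without it the Setx log2 fold change was −1.95 (SE 0.17, adjusted p = 5.29e-06). Its expression profile correlated with those of the 4 Setx-KO libraries of its age with r = 0.984 to 0.989 and with those of the 3 other WT libraries with r = 0.853 to 0.902, so counts of changed genes, list members and piRNA loci at 16 dpp are given with and without it. The labels do not say which part of Setx was removed, and the counts cover the whole gene.

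**Figure D1:**
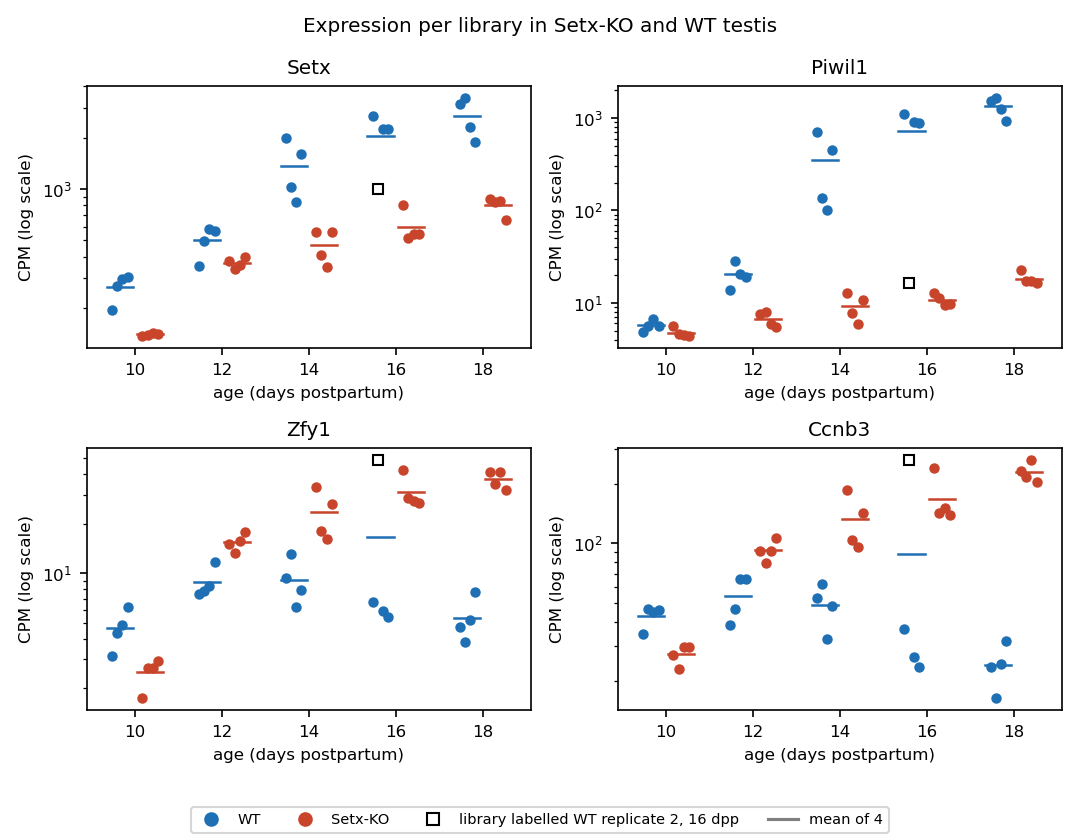
CPM of Setx, Piwil1, Zfy1 and Ccnb3 per library (log axis) against age in days postpartum, with WT in blue, Setx-KO in red, lines at the mean of the 4 libraries, and an open square for the library labelled WT replicate 2 at 16 dpp. Setx-KO values of Piwil1 stay low at all ages (mean 18.3 CPM at 18 dpp against 1340 in WT), while Zfy1 (37.4 against 5.37 CPM) and Ccnb3 (230 against 24 CPM) are higher in Setx-KO at 18 dpp.

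The 10 dpp comparison asks whether expression differed before pachytene. Few single genes differed. F13a1, a coagulation factor subunit made by macrophages, fell from 15.8 ± 1.75 CPM in WT to 8.36 ± 1.81 CPM in Setx-KO (log2 fold change −0.90, SE 0.14, adjusted p = 0.0346). Ccnb3, an X-linked B-type cyclin, fell from 42.9 ± 5.56 to 27.3 ± 3.07 CPM (−0.65, SE 0.1, adjusted p = 0.049). Atr, the kinase of the DNA damage response that acts on unsynapsed chromosomes, fell from 303 ± 27.1 to 223 ± 14.9 CPM (−0.44, SE 0.06, adjusted p = 0.0346). The fourth of the 4 changed genes among 15670 tested, 6820431F20Rik, rose by 0.45 (adjusted p = 0.0346) and is named after its value was seen. At an unadjusted p under 0.05 there were 2331 genes, and the groups did not overlap at 6.21% of genes, where chance gives 2.86%. The count of 4 depends on single libraries and on the tool. It was 656 without WT replicate 1, 341 without KO replicate 4, 0 without KO replicate 1 and 2 without KO replicate 2. It was 1 without KO replicate 3, WT replicate 3 or WT replicate 4. It was 252 with DESeq2's Wald test and 196 with limma-voom, each Benjamini-Hochberg adjusted. It was 0 with limma-trend on TPM (1917 at an unadjusted p under 0.05) and 0 in an edgeR fit of all 40 libraries (684 unadjusted). Within replicates 1 and 2 it was 54 genes, and within replicates 3 and 4 it was 734.

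The meiotic lists had medians below 0 at 10 dpp, while their members mostly passed the test only when adjusted over the list alone. For meiotic entry the median log2 fold change was −0.34, with 0 of 14 measured members past the test over all genes and 10 lower when adjusted over the list alone. For meiotic recombination it was −0.26, with 0 of 29 over all genes and 15 lower over the list alone. For synaptonemal complex and cohesin axis it was −0.39, with 0 of 20 and 15 lower. For pachytene and diplotene spermatocyte it was −0.24, with 0 of 20 and 8 lower. The camera adjusted p of these 4 lists was 6.94e-08, 1.20e-10, 4.40e-10 and 3.19e-04, and with an estimated correlation the adjusted p was 0.593 for each of the 4. The macrophage and leukocyte list had a median of −0.44, with 0 of 13 past the test over all genes and 7 lower over the list alone (camera adjusted p = 6.39e-06, adjusted p = 0.593 with an estimated correlation). WT replicate 1 stood apart from the other WT libraries in this list, and without it the median was −0.37 (camera adjusted p = 0.00348). The Sertoli cell list had a median of 0.13, with 0 of 25 past the test over all genes and, over the list alone, 9 higher and 1 lower (camera adjusted p = 0.0123, adjusted p = 0.699 with an estimated correlation). The piRNA pathway had 1 member lower over the list alone (median −0.11). The DNA damage response of silencing had Atr lower over all genes and 5 lower over the list alone (−0.11). X-linked genes had 1 higher and 8 lower over the list alone (−0.03), Y-linked genes 1 higher and 4 lower (−0.08) and Leydig cell 1 higher and 4 lower (−0.32). Spermatogonia (median 0.01), round spermatid (−0.19), retrogene copies (−0.10), R-loop factors (−0.03), p53 targets (−0.06), interferon response (−0.06), histones (−0.16), myoid (−0.20), endothelial (−0.22) and red blood cell (0.19) had 0 members past either test. Of the piRNA loci tested, 11 changed, namely 7 PPBI loci and 1 PPBD locus lower and 3 PrePP loci higher, and pi-Strbp_PPBI fell by 0.35 (SE 0.07, adjusted p = 0.0137). The count of 11 was 0 without KO replicate 3, WT replicate 3 or WT replicate 4 and 27 without WT replicate 1, and 2 of the 35 splits of the libraries, the real one included, gave as many.

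At 12 dpp 17 genes were lower in Setx-KO, among them 2 of the 23 measured pachytene and diplotene genes and 1 of the 31 piRNA pathway genes. Piwil1, the Piwi protein that binds pachytene piRNAs (ENSMUSG00000029423, chromosome 5, 128702524 to 128755474), fell from 20.5 ± 6.2 to 6.73 ± 1.23 CPM (log2 fold change −1.60, SE 0.23, adjusted p = 0.0398). Adam2, a sperm surface protein gene transcribed from pachytene on, fell from 5.13 ± 1.45 to 1.18 ± 0.196 CPM (−2.12, SE 0.26, adjusted p = 0.0015). Clgn, a testis chaperone of the endoplasmic reticulum, fell from 30.9 ± 6.02 to 16.3 ± 0.915 CPM (−0.92, SE 0.13, adjusted p = 0.0121). Zfy1, a Y-linked zinc-finger gene (ENSMUSG00000053211, 725128 to 797409), rose from 8.86 ± 1.91 to 15.5 ± 1.8 CPM (0.81, SE 0.14, adjusted p = 0.0321). Smpd5 (−2.42, SE 0.27), Fabp9 (−2.12, SE 0.23), Zmynd10 (−1.87, SE 0.26), Dkkl1 (−1.35, SE 0.21) and Gstt2 (−1.14, SE 0.15) also fell, and Sfi1 rose (0.40, SE 0.05), with edgeR Benjamini-Hochberg adjusted p from 8.62e-04 to 0.0105. Of 15796 genes, 20 changed, 3 higher and 17 lower, and 738 had an unadjusted p under 0.05. The groups did not overlap at 3.2% of genes, where chance gives 2.86%. All 17 lower genes were also lower at 14 dpp, against 0.199 from independent lists. With the replicate number as a block, 87 genes changed, the 20 among them. The count was 55 with DESeq2's Wald test, 171 without a filter on low counts, 59 with replicates 1 and 2 against 3 and 4 as a covariate, 6 with limma-trend on TPM and 0 in an edgeR fit of all 40 libraries (219 unadjusted). The count was 106 without the library labelled WT replicate 1 at 12 dpp, 13 without WT replicate 3 or KO replicate 3 and 10 without KO replicate 4, and within replicates 1 and 2 it was 8. Within replicates 3 and 4, 47 genes were higher and 82 lower.

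The lists fixed for these stages moved in few members at 12 dpp. In the pachytene and diplotene list (median −0.28), 2 of 23 measured members fell, 21 did not pass, and 6 fell when adjusted over the list alone (camera adjusted p = 1.06e-11, adjusted p = 0.593 with an estimated correlation). In the piRNA pathway (median −0.08), 1 of 31 fell, and 4 fell over the list alone (5.44e-06 by camera, adjusted p = 0.593 with an estimated correlation). With the replicate block these counts over all genes were 6 and 2. X-linked genes expressed before silencing (median 0.05) had 0 of 44 past the test and 7 higher over the list alone, and with the block 7 rose over all genes. Among Y-linked genes (median 0.10) 1 of 9 rose, 3 rose over the list alone, and 3 rose with the block. Their camera adjusted p was 6.39e-06 and 1.44e-06, and the adjusted p was 0.593 for both with an estimated correlation. Retrogene copies had 1 of 8 members lower over the list alone (median −0.04). The other lists had 0 members past either test without the block. Their medians were −0.02 for spermatogonia, 0.01 for meiotic entry, −0.01 for meiotic recombination, −0.02 for the axis, −0.26 for round spermatid and −0.01 for the silencing response. The medians were −0.02 for R-loop factors, −0.02 for p53 targets, 0.03 for interferon response and 0.02 for histones. Among other cell types they were 0.04 for Sertoli, −0.02 for Leydig, −0.10 for myoid, 0.07 for endothelial, −0.11 for macrophage and 0.13 for red blood cell. With the block, 2 of 14 Leydig members and 1 of 8 retrogene copies fell over all genes, 1 of 19 members of the silencing response rose, and the macrophage list (median −0.14) passed with camera, with an unadjusted p of 0.327 with an estimated correlation.

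At 14 dpp, 11 of 29 measured pachytene and diplotene genes were lower, and 3 of 44 X-linked and 2 of 9 Y-linked genes of the lists were higher. Ldhc, the testis lactate dehydrogenase (ENSMUSG00000030851, chromosome 7, 46861203 to 46878142), fell from 422 ± 389 to 6.17 ± 2.55 CPM (log2 fold change −6.10, SE 0.89, adjusted p = 0.0369). Acr, the acrosomal protease acrosin, fell from 17.8 ± 15 to 0.166 ± 0.0637 CPM (−6.65, SE 0.92, adjusted p = 0.0355). Piwil1 fell from 351 ± 288 to 9.35 ± 3.11 CPM (−5.23, SE 0.69, adjusted p = 0.0324), and Tdrd6, a tudor protein of germ granules, from 104 ± 100 to 1.29 ± 0.564 CPM (−6.34, SE 1.03, adjusted p = 0.0376). The largest falls were of Cmtm2a (−7.81, SE 1.42), Tmbim7 (−7.45, SE 1.27), Rbakdn (−7.29, SE 1.3), Fbp1 (−7.26, SE 1.15), Hrasls5 (−7.25, SE 1.43), Qrich2 (−7.22, SE 1.2), Tcp10b (−7.04, SE 1.24) and Pabpc2 (−7.01, SE 1.18). Zfy2 rose from 12.3 ± 3.68 to 35.3 ± 11.7 CPM (1.52, SE 0.28, adjusted p = 0.0377). Zfy1 rose from 9.16 ± 2.9 to 23.5 ± 8.11 CPM (1.36, SE 0.29, adjusted p = 0.0494) and Ccnb3 from 48.8 ± 12.3 CPM in WT (1.44, SE 0.25, adjusted p = 0.0377). Pcdh8 (2.17, SE 0.36), the X-linked Scml1 (1.48, SE 0.25), Tex13c2 (1.47, SE 0.29) and Rhox2b (1.18, SE 0.25), and Ky (1.16, SE 0.2) rose as well, with edgeR Benjamini-Hochberg adjusted p from 0.0376 to 0.0458. Of 16172 genes, 387 changed, 47 higher and 340 lower, 333 of the latter by at least 2-fold, and 11.56% did not overlap between groups (chance 2.86%). With the replicate block 1615 genes changed, 399 higher and 1216 lower. DESeq2's Wald test gave 1189, a fit of all 40 libraries 1542, limma-trend on TPM 86, edgeR without a filter on low counts 27, and replicates 1 and 2 against 3 and 4 as a covariate 1. The count was 0 without any KO replicate or without WT replicate 4, 43 without WT replicate 1, 668 without WT replicate 2 and 1076 without WT replicate 3. Within each pool of 2 against 2 it was 0, where the median of the pachytene list was −2.53 and −2.15. At an unadjusted p under 0.05 the count was 2758.

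In the pachytene and diplotene list, 11 of 29 measured members fell at 14 dpp, 18 did not pass, and 24 fell when adjusted over the list alone (median −2.30, camera adjusted p = 1.01e-13, adjusted p = 0.593 with an estimated correlation). In the piRNA pathway, 3 of 31 fell and 17 fell over the list alone (−0.63, 2.02e-07 by camera, adjusted p = 0.611 with an estimated correlation), among them Tdrd5 (−1.85, SE 0.37). Of the autosomal retrogene copies of X-linked genes, Gk2 (−6.25, SE 0.99), Cetn1 (−5.42, SE 0.93), Ppp3r2 (−5.26, SE 1.11) and Zfa-ps (−4.06, SE 0.61) fell, 4 of 12 members, and 5 fell over the list alone (median −0.75, camera adjusted p = 1.43e-05, adjusted p = 0.593 with an estimated correlation). X-linked genes expressed before silencing had 3 of 44 higher and 18 over the list alone (median 0.24), including Fmr1 (0.71, SE 0.14) and Tktl1 (0.91, SE 0.19). Y-linked genes had 2 of 9 higher and 6 over the list alone (0.42). Their camera adjusted p was 1.01e-13 and 1.55e-06, with 0.593 for both as adjusted p with an estimated correlation. With the replicate block the counts over all genes were 21 lower for pachytene, 18 lower for the piRNA pathway, 7 lower for retrogenes, 20 higher for X-linked and 4 higher for Y-linked genes. The block also placed 11 lower and 2 higher recombination genes, 7 lower and 1 higher axis genes and 5 lower meiotic entry genes past the threshold, where the fit without it placed 0, and the axis list (median −0.26) passed with camera, with an unadjusted p of 0.0297 with an estimated correlation. Scml2, an X-linked polycomb protein gene in the silencing response list, rose (0.72, SE 0.15), 1 of 19 members under either adjustment (median −0.11), and 5 others fell with the block. Papolb, a testis poly(A) polymerase, fell (−3.01, SE 0.59), 1 of 25 R-loop and termination members (median −0.13). With the block Papolb was at −2.70 and did not pass, while 2 others fell. Spermatogonia had 1 member lower over the list alone (median 0.14) and histones 1 higher (0.10). Meiotic entry (0.18), recombination (−0.09), axis (−0.28), round spermatid (−0.22), p53 targets (0.14), interferon response (−0.06), Sertoli (0.18), Leydig (−0.18), myoid (−0.05), endothelial (−0.12), macrophage (−0.09) and red blood cell (−0.55) had 0 members past either test. With the block, 3 p53 targets rose and 1 fell, 2 Sertoli genes rose, 1 spermatogonial gene rose and 1 fell, 1 interferon and 1 Leydig gene fell, and 1 histone gene rose.

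**Figure D2:**
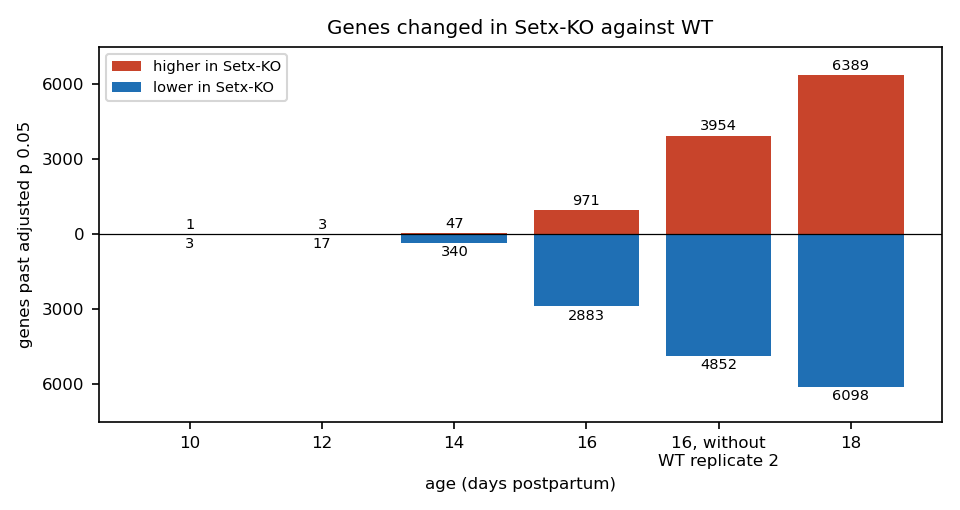
Number of genes past an adjusted p of 0.05 (edgeR, vertical axis) per age in days postpartum, with genes higher in Setx-KO drawn upward in red and genes lower in Setx-KO drawn downward in blue. The count grows from 4 genes at 10 dpp to 12487 at 18 dpp, and at 16 dpp it is 3854 with and 8806 without the library labelled WT replicate 2.

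At 16 dpp 23 of 26 measured pachytene and diplotene genes and 23 of 31 piRNA pathway genes were lower in Setx-KO. With all 8 libraries, Spata16, a spermatid gene, fell from 85.8 ± 71.7 to 0.349 ± 0.0876 CPM (log2 fold change −7.89, SE 1.42). Tdrd6 fell from 381 ± 297 to 1.62 ± 0.523 CPM (−7.87, SE 1.46) and Adam5, a sperm surface metalloprotease family gene, from 384 ± 294 to 1.27 ± 0.413 CPM (−8.21, SE 1.55). Ankar (−8.28, SE 1.5), Hspb9 (−7.91, SE 1.47), March11 (−7.81, SE 1.47), Atp8b3 (−7.72, SE 1.45) and Wdr63 (−7.47, SE 1.39) fell as well, and the edgeR Benjamini-Hochberg adjusted p of all 8 was 0.0257. The Y-linked Rbmy, an RNA-binding protein gene of germ cells, rose from 8.63 ± 2.3 to 18.5 ± 3.44 CPM (1.10, SE 0.21, adjusted p = 0.0257). Gpr50 (1.35, SE 0.36), Jsrp1 (1.24, SE 0.29), Shisa8 (1.11, SE 0.26), Syt12 (1.08, SE 0.3), Tnfrsf12a (1.04, SE 0.22), Igfbp3 (1.02, SE 0.15) and Lrfn3 (1.01, SE 0.23) rose. Without the library labelled WT replicate 2 (n = 3 WT), Ccnb3 rose from 27.9 ± 6.15 to 169 ± 54.1 CPM (2.60, SE 0.24), Zfy2 from 8.3 ± 1.37 to 45.5 ± 13.1 CPM (2.45, SE 0.22) and Zfy1 from 5.82 ± 0.507 to 31.4 ± 8.63 CPM (2.43, SE 0.22). Spon2 (2.96, SE 0.44), Tex13c2 (2.76, SE 0.24), Scml1 (2.41, SE 0.26), Fndc3c1 (2.17, SE 0.24) and H2bfm (2.10, SE 0.28) rose as well. In that comparison Ldhc fell from 1630 ± 464 to 7.76 ± 1.43 CPM (−7.71, SE 0.23) and Fbp1 from 288 ± 91.6 to 0.326 ± 0.189 CPM (−9.80, SE 0.32). Slc9c1 (−10.33), Cmtm2b (−10.19), Aqp9 (−10.10), Stpg4 (−10.10), Slco6c1 (−9.73), Cmtm2a (−9.62) and AY702103 (−9.57) fell with Setx-KO means between 0.0347 and 0.233 CPM. Of 16033 genes 3854 changed, 971 higher and 2883 lower, and on TPM with limma-trend the split was 1008 higher and 1685 lower, while limma-voom called 10088 and a fit of all 40 libraries 8629. Without that library 8806 of 16909 changed, 3954 higher and 4852 lower, and 57.19% did not overlap between groups (chance 5.71%), against 21.87% with it (chance 2.86%). The count was 0 when any of WT replicates 1, 3 and 4 or KO replicates 2, 3 and 4 was left out instead. It was 0 within replicates 1 and 2, which include the library, and 8453 within replicates 3 and 4. With all 8 libraries 6860 genes had an unadjusted p under 0.05.

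Most pachytene and piRNA pathway members fell at 16 dpp, and more X-linked members rose without the doubted library. In the pachytene and diplotene list 23 of 26 measured members fell, and adjusted over the list alone 23 fell and 1 rose (median −2.67, camera adjusted p = 1.20e-07, adjusted p = 0.593 with an estimated correlation). Without the library labelled WT replicate 2, 28 of 31 fell and 3 rose under either adjustment (−3.97). In the piRNA pathway 23 of 31 fell and 25 over the list alone (−1.07, 7.08e-08 by camera, adjusted p = 0.593 with an estimated correlation), among them Tdrd9 (−1.29, SE 0.22), Tdrd12 (−1.62, SE 0.26) and Mybl1, the transcription factor of pachytene piRNA genes (−0.95, SE 0.17). Without that library 24 fell and 2 rose (−1.20), 25 and 2 over the list alone. Retrogene copies had 9 of 12 lower, 10 over the list alone (−1.14, 8.40e-05 by camera, adjusted p = 0.593), and 12 of 13 lower without that library. X-linked genes had 9 of 44 higher and 0 over the list alone (0.49, 2.61e-08 by camera, adjusted p = 0.611 with an estimated correlation), and 42 of 44 higher without that library under either adjustment (0.72). Y-linked genes had 1 of 9 higher (0.55, 0.00406 by camera, adjusted p = 0.611), and 9 of 9 without that library (1.06). In meiotic recombination 12 of 29 fell, including Spo11, the enzyme that makes meiotic DNA breaks (−2.10, SE 0.42), and 1 rose and 13 fell over the list alone (median −0.22), against 7 higher and 12 lower without that library. In the axis list 9 of 20 fell, among them Sycp2 (−0.85, SE 0.16) and Stag3 (−0.71, SE 0.17), 12 over the list alone (−0.44), against 3 higher and 11 lower without it. The silencing response had 6 of 19 lower under either adjustment (−0.23), including Mdc1 (−1.12, SE 0.19) and Atr (−0.70, SE 0.14), and 4 higher and 6 lower without it.

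Among the other lists at 16 dpp, Sertoli cell genes had 6 of 25 higher and 18 over the list alone (median 0.51, camera adjusted p = 1.83e-06, adjusted p = 0.611 with an estimated correlation), and 20 without the library labelled WT replicate 2 (0.55). Spermatogonia had 6 higher and 1 lower of 24, 8 and 1 over the list alone (0.25), where Id4 fell (−1.81, SE 0.49) and Ccnd2 rose (0.51, SE 0.13), and 12 higher and 2 lower of 25 without that library. Meiotic entry had 3 of 14 lower, 1 higher and 3 lower over the list alone (0.27), with Meioc at −0.62 (SE 0.13), and 9 higher and 3 lower without it. R-loop factors had 10 of 25 lower, 11 over the list alone (−0.23), and 3 higher and 12 lower without it. The p53 targets had 4 higher and 1 lower of 19 under either adjustment (0.38), and 12 higher and 2 lower without it, and interferon response had 2 of 23 lower under either adjustment (0.27), and 9 higher and 2 lower of 24 without it. Leydig cell had 1 of 14 higher (0.28), and 3 higher and 1 lower without it. Macrophage (0.23), endothelial (0.11), red blood cell (−0.07), histones (0.37), myoid (0.29) and round spermatid (−0.19) had 0 members past either test with all libraries. Without that library 2 macrophage genes, 1 endothelial gene, 1 red blood cell gene and 2 histone genes rose, 2 round spermatid genes fell, and 0 of 10 myoid genes changed.

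At 18 dpp most tested genes differed, and 29 of 31 pachytene and diplotene genes were lower in Setx-KO. Ldhc fell from 2780 ± 1000 to 14.5 ± 2.04 CPM (log2 fold change −7.58, SE 0.34, adjusted p = 3.08e-06), Piwil1 from 1340 ± 323 to 18.3 ± 3 CPM (−6.19, SE 0.24, adjusted p = 2.40e-06) and Acr to 0.511 ± 0.16 CPM (−7.93, SE 0.38, adjusted p = 3.20e-06). Qrich2, a sperm tail protein gene, fell from 1040 ± 546 to 0.936 ± 0.174 CPM (−10.11, SE 0.55) and Cmtm2a from 412 ± 188 to 0.267 ± 0.187 CPM (−10.55, SE 0.56). Bpi (−10.78, SE 0.67), Toporsl (−10.73, SE 0.87), Ccdc7a (−10.63, SE 0.82), Ccdc7b (−10.55, SE 0.79), Prdx6b (−10.36, SE 0.63) and Slco6c1 (−10.17, SE 0.62) completed the 8 largest falls. Ccnb3 (ENSMUSG00000051592, chromosome X, 6979652 to 7041619) rose from 24 ± 6.41 to 230 ± 25.4 CPM (3.26, SE 0.2, adjusted p = 3.43e-06). Zfy2 rose from 8.27 ± 2.16 to 59.1 ± 7.57 CPM (2.83, SE 0.2, adjusted p = 6.50e-06) and Zfy1 from 5.37 ± 1.64 to 37.4 ± 4.65 CPM (2.79, SE 0.21, adjusted p = 8.75e-06). Spon2, a secreted matrix protein gene, rose from 0.786 ± 0.359 to 10.5 ± 2.74 CPM (3.70, SE 0.32), and Tex13c2 (3.09, SE 0.25), Fndc3c1 (2.80, SE 0.2), Dmrtc1c1 (2.77, SE 0.65) and Cyp4f17 (2.73, SE 0.18) rose too. Of 17020 genes 12487 changed, 6389 higher and 6098 lower, with 1935 higher and 3708 lower by at least 2-fold, and 69.54% did not overlap between groups (chance 2.86%). The count was 11072 to 13777 when any library was left out, 14514 within replicates 1 and 2 and 8605 within replicates 3 and 4. Scaling moved the balance of directions, since the median over all genes was 0.15 with TMM, 0.03 with DESeq2's size factors and 0.45 with TPM. The TPM fit called 9171 higher and 4382 lower, while edgeR without a filter on low counts called 5280 higher and 7616 lower.

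Among germ cell lists at 18 dpp, 29 of 31 pachytene and diplotene members fell and 1 rose under either adjustment (median −4.02, camera adjusted p = 6.16e-11, adjusted p = 0.593 with an estimated correlation). In the piRNA pathway 26 of 31 fell and 3 rose under either adjustment (−1.41, 1.44e-06 by camera, adjusted p = 0.593 with an estimated correlation), with Tdrd6 at −8.39 (SE 0.48), Pld6 at −3.19 (SE 0.18) and Tdrd5 at −3.05 (SE 0.15). All 44 X-linked genes rose (1.19, camera adjusted p = 1.40e-10, adjusted p = 0.611 with an estimated correlation), including Tktl1 (2.52, SE 0.19), Fmr1 (2.13, SE 0.16) and Usp9x (1.55, SE 0.13). Of 9 Y-linked genes 8 rose (1.63, 8.60e-04 by camera, adjusted p = 0.593 with an estimated correlation), with Usp9y at 1.74 (SE 0.1) and Eif2s3y at 1.63 (SE 0.17). Of 13 retrogene copies 12 fell (−1.58, 1.50e-05 by camera, adjusted p = 0.593 with an estimated correlation), including Ppp3r2 (−8.57, SE 0.48), Cetn1 (−7.80, SE 0.42) and Gk2 (−7.41, SE 0.45). The X-linked, Y-linked and retrogene counts were equal over all genes and adjusted over the list alone. Recombination genes moved both ways, with 10 of 29 higher and 13 lower, among the latter Spo11 (−2.51, SE 0.18), Psmc3ip (−1.94, SE 0.16), Mlh3 (−1.72, SE 0.14) and Hsf2bp (−1.56, SE 0.13). Axis genes had 5 higher, with the meiotic cohesin Rec8 at 1.10 (SE 0.12), and 12 lower of 20, with Syce1 at −2.48 (SE 0.24), Ccdc155 at −2.04 (SE 0.16) and Majin at −1.13 (SE 0.11). The silencing response had 3 higher and 7 lower of 19, 3 and 6 over the list alone, where Scml2 (2.14, SE 0.16) and Brca1 (0.76, SE 0.12) rose and Mdc1 (−1.37, SE 0.15) and Rad9b (−1.03, SE 0.11) fell. R-loop and termination factors had 4 higher and 12 lower of 25, with Papolb (−6.55, SE 0.49), Rnaseh2a, a subunit of the RNase that cleaves RNA:DNA hybrids (−3.54, SE 0.33), Rnaseh2c (−1.21, SE 0.14) and Upf1 (−1.12, SE 0.11) falling. The medians of the recombination, axis, silencing response and R-loop lists were −0.05, −0.32, −0.12 and −0.19 with TMM, −0.17, −0.44, −0.24 and −0.32 with DESeq2's size factors, and above 0 with TPM, at 0.38, 0.12, 0.31 and 0.17.

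Among lists of other testis cells at 18 dpp, Sertoli cell genes rose in 24 of 25 cases under either adjustment (median 1.04, camera adjusted p = 2.71e-05, adjusted p = 0.696 with an estimated correlation), with Kitl at 1.17 (SE 0.2), Mro at 1.06 (SE 0.2) and Amhr2 at 0.97 (SE 0.19). Leydig cell genes rose in 9 of 14 (0.97), with Star, which brings cholesterol into mitochondria, at 1.14 (SE 0.23), and macrophage genes in 10 of 13 (0.88), with Mrc1 at 0.88 (SE 0.19). Endothelial genes rose in 3 of 10 (0.48, with Tie1 at 0.64, SE 0.15) and myoid genes in 1 of 10 (0.42, Des at 0.61, SE 0.24), which became 0 over the list alone, while the other 3 counts stayed. Red blood cell genes rose in 0 of 5 (0.76). The camera adjusted p was 0.0287 for macrophages (adjusted p = 0.711 with an estimated correlation), 0.0651 for Leydig, 0.0692 for endothelial, 0.168 for myoid and 0.464 for red blood cells. Of the epididymis list 2 of 12 genes were measured and 1 rose, Defb15, from 0.0194 ± 0.0389 to 0.811 ± 0.0886 CPM. Spermatogonial genes rose in 16 of 23 and fell in 2 under either adjustment (0.70), with Sall4 at 1.06 (SE 0.19), Kit at 0.97 (SE 0.17), Dmrtb1 at −2.45 (SE 0.32) and Id4 at −2.26 (SE 0.13). Meiotic entry genes rose in 9 of 14 and fell in 2 (0.80), with Ugt8a at 1.15 (SE 0.14) and Meioc at −0.89 (SE 0.12). The p53 targets rose in 13 of 19 and fell in 3 under either adjustment (0.86), with Eda2r at 2.45 (SE 0.33), the cell cycle inhibitor Cdkn1a at 1.46 (SE 0.16), Ccng1 at 1.34 (SE 0.17) and Plk2 at 1.13 (SE 0.16). Interferon response genes rose in 5 of 27 and fell in 2 (0.42), 0 and 2 over the list alone, with Dhx58 at −4.52 (SE 0.37) and Stat2 at −1.19 (SE 0.17). All 5 measured histone genes rose under either adjustment (1.24), with Hist1h4i at 2.30 (SE 0.29), and poly(A) selection captures such transcripts poorly. Round spermatid genes fell in 2 of 5 (−1.75), Gsg1 (−7.99, SE 1.23) and Tssk1 (−2.42, SE 0.5). Over all ages 44 of the 106 list tests passed with camera, 0 with an estimated correlation and 20 with fry, which tests whether a list's genes move, on balance, one way. Median and camera direction differed in sign for red blood cell at 10 and 16 dpp, recombination, silencing response, R-loop and histones at 12 dpp and interferon response at 14 dpp, none of them past the threshold.

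**Figure D3:**
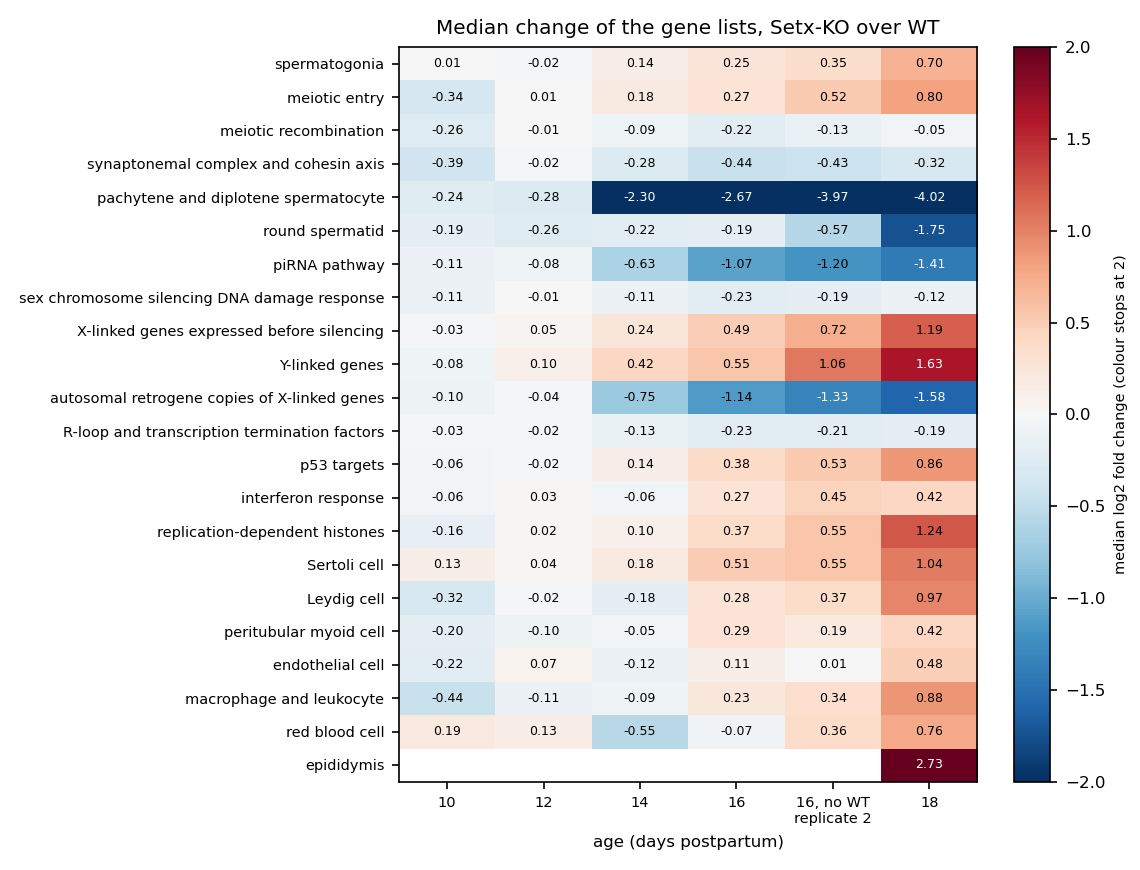
Median log2 fold change of Setx-KO over WT (colour, stopping at 2 in either direction, with the value printed) for each of the 22 gene lists (vertical axis) at each age in days postpartum (horizontal axis), with 16 dpp also shown without the library labelled WT replicate 2. The pachytene and diplotene list falls to −4.02 at 18 dpp, the X-linked list reaches 1.19, and the recombination, axis, silencing response and R-loop lists, below 0 here at 18 dpp, are above 0 with TPM.

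The X chromosome is silenced in pachytene spermatocytes. X-linked genes as a set stood above autosomal genes in Setx-KO from 12 dpp on by camera at its preset correlation. The X-linked minus autosomal median log2 fold change was −0.02 at 10 dpp, 0.04 at 12 dpp, 0.23 at 14 dpp, 0.44 at 16 dpp and 1.04 at 18 dpp, and 0.59 at 16 dpp without the library labelled WT replicate 2. The camera adjusted p over the 5 ages (limma, Benjamini-Hochberg) was 0.0656, 6.31e-06, 7.97e-26, 3.96e-22 and 3.55e-25 in that order, and 2.04e-26 at 16 dpp without that library. With an estimated correlation the adjusted p was 0.223, 0.0767, 0.0767, 0.205 and 0.205, and 0.0603 at 16 dpp without that library. Of X-linked genes 44.55%, 64.9%, 88.92%, 97.21% and 97.8% lay above 0 at the 5 ages, and of autosomal genes 49.45%, 48.68%, 47.84%, 52.5% and 52.46%. At 18 dpp 597 of 682 X-linked genes were higher and 8 lower, 14 of 18 Y-linked genes were higher, and 5766 of 16290 autosomal genes were higher. At 16 dpp without that library 496 of 691 X-linked genes were higher, against 95 of 682 with it, and at 14 dpp 32 of 686 were. With the replicate block 19.24% of the 686 were higher at 14 dpp and 21 of 678 at 12 dpp, where the fit without the block called 0. Against WT at 10 dpp, the X-linked minus autosomal median of WT was −0.02, −0.28, −0.45 and −1.14 at 12, 14, 16 and 18 dpp, while that of Setx-KO was −0.03, 0.02, 0, 0.02 and 0.01 at 10, 12, 14, 16 and 18 dpp. Within the pools of replicates 1 and 2 and of 3 and 4, the Setx-KO over WT difference was −0.05 and −0.02 at 10 dpp, 0.05 and 0.04 at 12 dpp, 0.27 and 0.22 at 14 dpp, 0.39 and 0.55 at 16 dpp, and 1.43 and 0.84 at 18 dpp. The pachytene list, whose cells carry the silenced X, was lower in Setx-KO over the same ages (median −0.28 at 12 dpp and −4.02 at 18 dpp), and the Sertoli list higher (0.04 and 1.04).

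**Figure D4:**
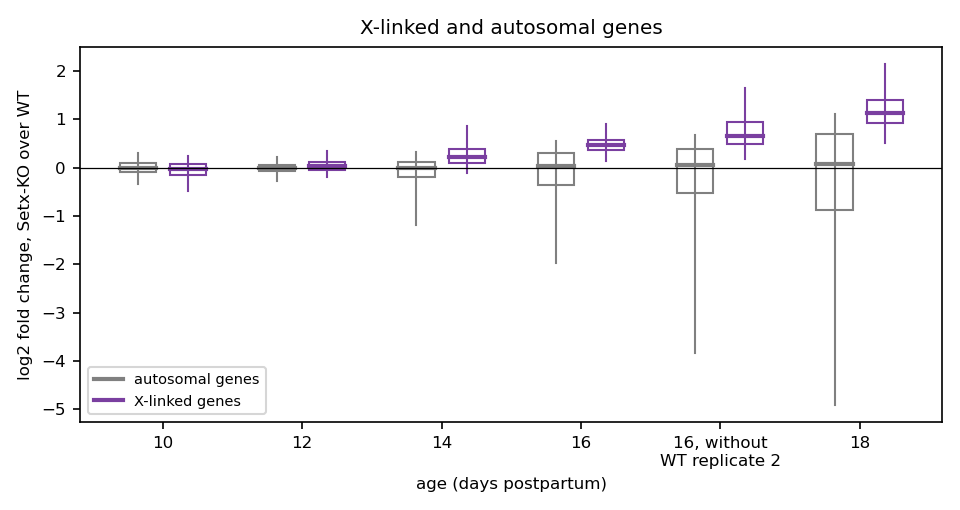
Log2 fold change of Setx-KO over WT (vertical axis) for autosomal genes in grey and X-linked genes in purple, by age in days postpartum, where thick lines are medians, boxes the middle 50% of genes and thin lines the 5th to 95th percentile. The X-linked median moves from −0.02 at 10 dpp to 1.12 at 18 dpp and the autosomal median from 0 to 0.08.

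The piRNA loci, transcribed to piRNA precursors, differed by class. Mean sums of PPBD and PPBI loci were lower in Setx-KO at all 5 ages. Those of PrePP loci were higher at 10 and 12 dpp and lower from 14 dpp on. Loci with the suffix PPBD summed to 94 ± 11.9 CPM in WT and 82.2 ± 1.82 in Setx-KO at 10 dpp (exact permutation p = 0.0857). They summed to 282 ± 68.5 against 122.5 ± 10.4 at 12 dpp, 1880 ± 1280 against 246 ± 89.2 at 14 dpp, 3900 ± 2360 against 310 ± 43.8 at 16 dpp and 7730 ± 2270 against 618 ± 199 at 18 dpp. Without the library labelled WT replicate 2 at 16 dpp, the WT sums there were 4980 ± 1120 CPM for PPBD, 8260 ± 1480 for PPBI and 9510 ± 390 for PrePP (n = 3). The exact permutation p at these 4 ages was 0.0286, its minimum. PPBI loci summed to 950 ± 56.3 against 867 ± 11.1 CPM at 10 dpp and 1340 ± 120 against 1210 ± 49.2 at 12 dpp (exact permutation p = 0.0571 and 0.143). At 14, 16 and 18 dpp they summed to 3930 ± 2020 against 1480 ± 236, 6780 ± 3190 against 1670 ± 218 and 11400 ± 2960 against 2200 ± 207 (exact permutation p = 0.0286 each). PrePP loci stayed between 9230 and 9640 CPM in WT and 8600 and 10100 in Setx-KO, with exact permutation p = 0.114, 0.171, 0.2, 0.0286 and 0.286. Adjusted over these 15 tests (Benjamini-Hochberg), the 8 exact permutation p of 0.0286 became 0.0536. The tests ignore the pairing at 12 and 14 dpp, under which p cannot fall under 0.05. Within the pools the WT over Setx-KO ratio of PPBD was 1.03 and 1.25 at 10 dpp, 2.16 and 2.45 at 12 dpp, 8.45 and 6.64 at 14 dpp, 10.1 and 15.7 at 16 dpp, and 12.4 and 12.7 at 18 dpp.

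Of single loci, 43 of 176 tested changed at 12 dpp, with 20 of 24 PPBD and 22 of 54 PPBI lower and 1 PrePP higher. With the replicate block 18 PPBD and 18 PPBI were lower at 12 dpp and 0 PrePP changed. The locus 5-qG3-23659_PPBD fell from 4.16 ± 1.87 to 0.0231 ± 0.0463 CPM (log2 fold change −6.90, SE 0.75, adjusted p = 6.37e-06) and pi-1700016M24Rik_PPBD from 10.2 ± 4.43 to 0.605 ± 0.195 CPM (−4.06, SE 0.4, adjusted p = 5.33e-06). At 14 dpp 109 of 212 changed, with 47 of 50 PPBD, 51 of 64 PPBI and 7 PrePP lower and 4 PrePP higher. With the replicate block 49 PPBD, 53 PPBI and 12 PrePP were lower and 14 PrePP higher. The locus 2-qF1-2536_PPBI fell from 110 ± 82.7 to 0.16 ± 0.102 CPM (−9.29, SE 0.84, adjusted p = 5.56e-04). At 16 dpp 88 of 170 changed, with 15 of 16 PPBD, 50 of 56 PPBI and 15 PrePP lower and 1 PPBI and 7 PrePP higher. Without the library labelled WT replicate 2, 166 of 213 changed, with 49 of 50 PPBD, 61 of 65 PPBI and 17 PrePP lower and 1 PPBI and 38 PrePP higher. At 18 dpp 184 of 213 changed, with 48 PPBD, 60 PPBI and 17 PrePP lower and 1, 1 and 57 higher. There 14-qC1-1261_PPBD fell to 0.0887 ± 0.0372 CPM (−10.52, SE 0.4) and 5-qG3-23659_PPBD from 166 ± 36.2 to 0.497 ± 0.102 CPM (−8.36, SE 0.27). In contrast pi-Tfcp2l1_PrePP rose from 14.6 ± 2.91 to 45.8 ± 3.16 CPM (1.64, SE 0.15) and pi-Mafg_PrePP from 39.5 ± 7.59 to 110 ± 9.91 CPM (1.48, SE 0.15). Scaled to the piRNA table itself, the split of higher and lower loci was 69 and 92 at 14 dpp, 53 and 67 at 16 dpp and 95 and 104 at 18 dpp. Scaled to the gene table, 4, 8 and 59 loci were higher at these ages, of 109, 88 and 184 changed, and 39 of 166 at 16 dpp without the library labelled WT replicate 2.

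**Figure D5:**
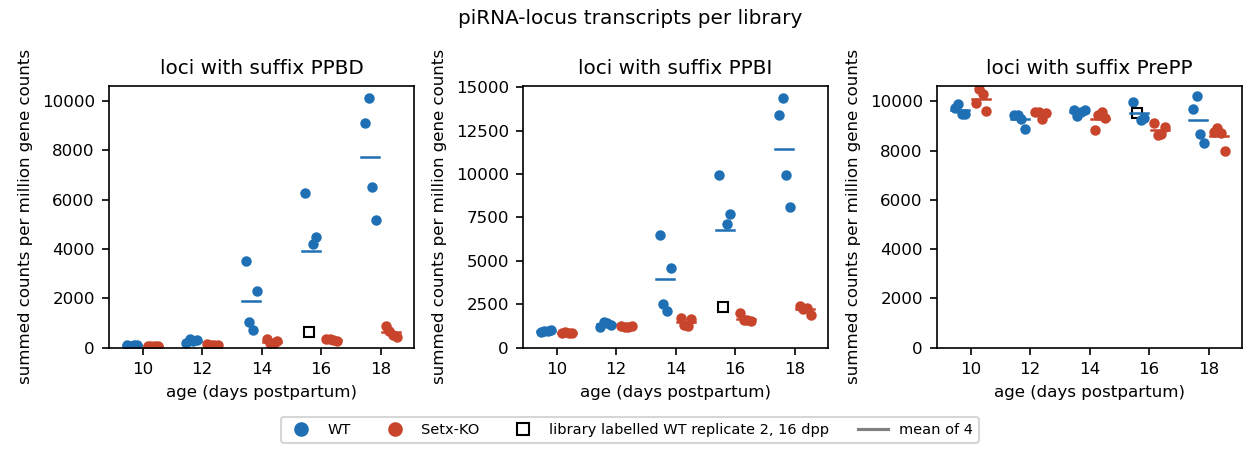
Summed CPM of the piRNA loci (vertical axis, from 0) per library against age in days postpartum, for the suffixes PPBD, PPBI and PrePP, with WT in blue, Setx-KO in red, lines at the mean of 4 and an open square for the library labelled WT replicate 2 at 16 dpp. PPBD rises to 7730 CPM in WT at 18 dpp and to 618 CPM in Setx-KO, while PrePP stays between 8600 and 10100 CPM in group means.

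WT development gives the background for Setx-KO. Between 12 and 14 dpp 931 of 17701 genes changed in WT, 882 of them higher, including Ldhc (log2 fold change 5.12, SE 1.05), Piwil1 (4.08, SE 0.83), Tdrd6 (5.74, SE 1.18), Spata4 (5.26, SE 1.05) and Setx (1.44, SE 0.3), each with edgeR Benjamini-Hochberg adjusted p = 0.0255. In this step 20 of 31 pachytene and diplotene genes and 11 of 31 piRNA pathway genes rose (medians 2.5 and 0.72), or 25 and 18 without the library labelled WT replicate 2 at 16 dpp (2.47 and 0.7). Between 10 and 12 dpp 6 genes changed, among list members Gml (2.15, SE 0.34) and Meiob, a single-strand DNA binding protein of recombination (1.22, SE 0.21). A fit of the 8 libraries of those ages called 1716. Between 14 and 16 dpp edgeR called 0 genes and DESeq2's Wald test 36, and edgeR called 4965 without the library labelled WT replicate 2. Between 16 and 18 dpp 8324 genes changed, 3635 higher and 4689 lower, or 4605 and 3883 with DESeq2's size factors, and 4954 without that library. An edgeR fit of the 8 libraries of 16 and 18 dpp called 0 genes (6290 at an unadjusted p under 0.05), and DESeq2's Wald test in the 20 libraries 8646. In the fit of 20 libraries 42 of 44 X-linked genes fell (median −0.82), 7 of 9 Y-linked genes (−0.97), 21 of 25 Sertoli genes (−0.75), 17 of 25 spermatogonial genes (−0.76) and 9 of 10 myoid genes (−0.72). Genes that fell included Sall4 (−1.08, SE 0.16), Stra8 (−0.87, SE 0.18) and Kit (−0.77, SE 0.15). Without that library 25, 4, 14, 17 and 9 members of the same lists fell. The X-linked minus autosomal median changed by −0.02, −0.26, −0.21 and −0.73 over the 4 steps, and by −0.02, −0.26, −0.41 and −0.50 without that library. The WT 12 to 14 dpp count was 10 without a filter on low counts, 4 with the replicate block, 1857 with DESeq2's Wald test, 2119 without WT replicate 3 at 14 dpp, 1953 without the library labelled WT replicate 2 at 16 dpp, and 1 to 4 without any of the 4 libraries of 12 dpp or of WT replicates 1 and 4 at 14 dpp. The 16 to 18 dpp count was 3759 and 3374 without WT replicates 1 and 2 at 18 dpp. The 10 to 12 dpp count was 12 without WT replicate 4 and 0 without replicate 2 at 10 dpp, 1 and 2 without replicates 1 and 3 at 10 dpp, 10 without replicate 1 at 12 dpp and 0 without replicate 2, 3 or 4 at 12 dpp.

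Across genes, the Setx-KO effect correlated negatively with the WT change at the neighbouring ages, with no library shared between the values correlated. Pearson's r (and Spearman's rho) was −0.255 (−0.291) at 10 dpp with the WT change from 12 to 14 dpp, −0.405 (−0.14) at 12 dpp with that from 10 to 14 dpp, and −0.874 (−0.692) at 14 dpp with that from 12 to 16 dpp. It was −0.833 (−0.867) at 16 dpp with that from 14 to 18 dpp, and −0.864 (−0.801) at 18 dpp with that from 14 to 16 dpp. Other splits of the 8 libraries of an age gave a median size of r of 0.123, 0.18, 0.518, 0.763 and 0.733 at the 5 ages in order. Genes are not independent replicates, so these 5 relations carry no p-value. Without the library labelled WT replicate 2 at 16 dpp r was −0.878, −0.841 and −0.905 at 14, 16 and 18 dpp.

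The Setx-KO effect differed among the 5 ages at 10085 of 18205 genes, and at 10673 of 18480 without the library labelled WT replicate 2 at 16 dpp. Rnaseh2a had a log2 fold change of 0.14, −0.06, −0.23, −1.58 and −3.56 at 10, 12, 14, 16 and 18 dpp, and Arc, an immediate-early gene, of 0.09, 0.02, −0.11, −2.02 and −4.11. Atoh8 (−0.04 at 10 dpp and −3.06 at 18 dpp), Cacna1h (0.10 and −2.89), Ttll1 (0.12 and −2.46), Krba1 (0.27 and −2.36) and Ralgps1 (0.26 and −2.31) ended lower, and Epop (−0.22 and 1.38) ended higher, each with edgeR interaction adjusted p = 2.51e-06 (Benjamini-Hochberg). Between successive ages the effect differed at 0, 0, 0 and 3774 genes, the last 1866 rising and 1908 falling, with 348, 1451, 1716 and 6862 at an unadjusted p under 0.05. Without that library these counts were 0, 193, 1669 and 1005.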

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

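The tests of a wrong label, of delayed development and of a lower germ cell share were chosen only after the results were seen. In this part CPM and list means (mean log2 CPM) are scaled over all 40 libraries.

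The library labelled WT replicate 2 at 16 dpp lay with the Setx-KO libraries, at 16.7 CPM of Piwil1 against 872 to 1070 in the other WT and 9.41 to 13 in the Setx-KO libraries of its age. A WT testis delayed in development is argued against by 627 genes at which every Setx-KO library of 18 dpp lay above the other 19 WT libraries. The doubted library lay above those 19 at 71.6% of these genes, and the highest share by the same count was 22.6% in another WT library (SD 5.5). The mean log2 CPM of 660 genes higher in every Setx-KO library at 14 and 18 dpp was 5.48, against at most 5.29 in the other WT libraries, a gap below the largest within-group SD of 0.26. A single wrong label may be the cause, since 90.6% of the 660 genes lay nearer to the Setx-KO mean of 16 dpp (at most 6.21% in another WT library of that age) and Setx, at 1010 CPM, lay inside the 95% prediction interval of the Setx-KO libraries (282 to 1240) and outside that of the other WT libraries (1480 to 3660). A mixture of WT and Setx-KO material cannot be told apart from it, because the WT share implied by 927 genes lower in Setx-KO was 2.51% (median, 5th to 95th percentile −8.96% to 36.1%) and that implied by Setx 23.5%. File names give it the same animal number as KO replicate 2 at 16 dpp, from which its counts differed more (chi-square per gene 19.2) than those of the 4 Setx-KO libraries did from each other (3.73 to 17.6). Its chi-square per gene was 5.02 against KO replicate 1, 20.1 against KO replicate 3 and 17.3 against KO replicate 4. Against the other WT libraries of 16 dpp it was 73.3 to 140.

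X-linked genes stood above autosomal genes in Setx-KO at 14 to 18 dpp. A smaller share of late spermatocytes cannot be told apart from other causes by the X-linked minus autosomal median of Setx-KO at 18 dpp over WT at 10 dpp, which was 0.01 (0 to 0.04 without single libraries), between the bounds set in advance. X-linked genes that follow the WT time course like autosomal genes stay open too, since the X-linked median at 16 dpp minus that of matched autosomal genes was 0.11, with 0.06 to 0.21 without single libraries. Transcription of sex-linked genes above any WT age may add to it. Every Setx-KO library of 18 dpp lay above all 20 WT libraries at 26 of 590 X-linked, 0 of 16 Y-linked and 1.89% of 13988 autosomal genes. The one-sided Fisher's exact p was 2.04e-04 for 4.29% of 606 sex-linked genes, but genes are not independent replicates. Without the library labelled WT replicate 2 at 16 dpp the sex-linked and autosomal shares were 23.1% and 3.47%.

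Meiotic gene lists had medians below 0 in Setx-KO at 10 dpp. A lower share of all germ cells, which would lower spermatogonial genes alike and raise those of other cells, is argued against by spermatogonia, with a median of 0.01 (−0.04 to 0.07 without single libraries, SD of members 0.151) against −0.39 to −0.24 in the 4 meiotic lists. From list means per library, the Setx-KO effect on 24 spermatogonial genes minus that on 82 meiotic genes was 0.305 (95% interval 0.0833 to 0.527), and 1 of 35 splits, the real one, was as large (highest other 0.287). Of 5 lists of other testis cells 4 had medians below 0, with −0.44 for macrophages (−0.61 to −0.31 without single libraries, −0.37 without WT replicate 1, which stood apart), −0.32 for Leydig (−0.38 to −0.27), −0.22 for endothelial (−0.26 to −0.11) and −0.20 for myoid cells (−0.27 to −0.11), and camera adjusted p of 6.39e-06, 0.00959, 0.0051 and 0.00167. Sertoli cells had 0.13 (0.09 to 0.17), and none of the 5 passed with an estimated correlation. The gap between the highest and lowest Setx-KO effect of these 5 lists, taken from means over members and not medians, was 0.501 and was reached by 2 of 35 splits (highest other 0.505), so that gap alone decides nothing. Fewer meiotic cells among the germ cells stay open. Setx-KO testes less advanced in the first wave at 10 dpp may be the source, since over 61 genes of the meiotic entry, recombination and axis lists the Setx-KO effect correlated with the WT change from 10 to 12 dpp at a mean r of −0.852 (−0.92 to −0.741 over 6 ways to divide the WT libraries). That correlation is across genes, which are not independent replicates, and it is not set beside other splits of the libraries. Litter and body weight are not in the labels, so a difference in these was not tested.

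Other splits of the same libraries were fitted for each model across genes. Of the 35 splits, 1 each, the real one, was as large for the counts of changed genes at 16 dpp (3854, highest other 2849) and 18 dpp (12487 and 0). At 10 dpp 3 splits gave as many as the 4 real genes, and the highest other, 219, exchanged WT replicate 1 and KO replicate 4. For piRNA loci 2 splits were as large at 10 dpp (11, highest other 18), and 1 each at 16 (88 and 73) and 18 dpp (184 and 0). For X-linked genes 8 were as large at 10 dpp (0.0213, highest other 0.0368), and 1 each at 16 (0.437 and 0.435) and 18 dpp (1.04 and 0.734). For lists past the threshold the numbers were 1 at 10 dpp (12, highest other 10), 13 at 16 dpp (12 and 17) and 19 at 18 dpp (9 and 15). For the size of the correlation with WT change they were 3 at 10 dpp (0.255, highest other 0.265), 8 at 16 dpp (0.833 and 0.857) and 1 at 18 dpp (0.864 and 0.862). At 12 and 14 dpp the libraries were treated as paired by replicate number. The 8 splits that part every pair are too few for a share under 0.05. Among these 8 the real value and the highest other were 20 and 1 changed genes at 12 dpp and 387 and 0 at 14 dpp, and 43 and 4 piRNA loci and 109 and 0. They were 0.0401 and 0.0397, and 0.228 and 0.176, for X-linked genes, 4 and 7, and 8 and 9, for lists past the threshold, and 0.405 and 0.473, and 0.874 and 0.882, for the correlation. The number as large was 1 for genes, piRNA loci and X-linked genes at both ages, 4 for the lists at both ages, and 2 and 3 for the correlation. Among splits that part fewer pairs, the highest count of changed genes was 324 at 14 dpp and 999 at 12 dpp, where replicates 1 and 2 were set against 3 and 4, which points to a structure of the samples, and the replicate block gave 87. For the difference among ages 5 of 40 groupings, the real one included, were as large (10085, highest other 12189). The 4 others all kept the 18 dpp split or exchanged its labels in full, so they still held the 18 dpp difference of genotypes. In WT 1 of 35 was as large for 10 to 12 dpp (6 and 0) and for 12 to 14 dpp (931 and 0), 35 for 14 to 16 dpp (0, highest other 7109, which moves the library labelled WT replicate 2 at 16 dpp to 14 dpp) and 2 for 16 to 18 dpp (8324 and 10186). A number as large of 1 is the lowest that 35 splits can give, and it was not adjusted over these results. At 18 dpp 12487 genes and 184 piRNA loci stood against 0 in every other split, which argues against chance. Chance stays open where the real value lay close to the highest other, as for X-linked genes at 16 dpp and the correlation at 18 dpp. At 10 dpp this holds for the lists and for the difference between spermatogonial and meiotic genes. Chance also stays open for WT from 10 to 12 and 12 to 14 dpp, whose counts fell to 0 and 1 without single libraries. The same holds for changed genes at 16 dpp, whose count of 3854 fell to 0 without single libraries, and wherever more than 1 split was as large.

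Of 280 tests of a library against the other 3 of its group, 23 found a library apart, where chance gives about 1 in 20, or 14. The gap to the nearest other library, as a share of the group's range, was above the 95% critical value of Dixon's test in each. In the library labelled WT replicate 2 at 16 dpp it was 0.831 for pachytene (3.29 against 6.68 to 7.37), 0.854 for the piRNA pathway (5.64 against 6.82 to 7.02), 0.919 for Y-linked genes (5.89 against 4.39 to 4.52), 0.84 for retrogenes (3.89 against 6.45 to 6.94) and 0.928 for red blood cells (3.81 against 2 to 2.13). In KO replicate 1 at 16 dpp it was 0.904 for Setx (808 CPM against 516 to 544), 0.833 for PPBI loci (1990 CPM against 1510 to 1590), 0.872 for spermatogonia (4.26 against 4.33 to 4.34), 0.84 for the piRNA pathway (5.57 against 5.31 to 5.35) and 0.89 for Y-linked genes (6 against 5.6 to 5.65). At 10 dpp it was 0.877 for macrophages in WT replicate 1 (2.84 against 2.36 to 2.42). At 12 dpp it was 0.984 for R-loop factors in WT replicate 1, 0.909 for PPBD loci and 0.918 for retrogenes in KO replicate 1, 0.877 for total counts and 0.834 for Y-linked genes in KO replicate 3, and 0.902 for X-linked minus autosomal expression in KO replicate 4. At 14 dpp it was 0.835 for macrophages in WT replicate 2 (3.39 against 2.61 to 2.74) and 0.848 for X-linked genes in KO replicate 3. At 16 dpp it was 0.893 for Sertoli cells in WT replicate 1 (5.86 against 6.48 to 6.55). At 18 dpp it was 0.865 for interferon response in WT replicate 4 (3.02 against 1.81 to 1.97), and for the epididymis list 0.927 in WT replicate 2 and 0.83 in KO replicate 3. Of 281 named genes, the number with a library apart was 24 in WT and 19 in Setx-KO at 10 dpp, 20 and 15 at 12 dpp, 19 in Setx-KO at 14 dpp, 53 in WT at 16 dpp (43 of them in replicate 2), 22 in Setx-KO at 16 dpp (19 of them in replicate 1) and 16 in Setx-KO at 18 dpp. In WT at 14 and 18 dpp it was 6 and 11, under the 1 in 20 that chance gives.

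The Setx-KO effect differed between ages by interaction tests, among the 5 ages at 10085 genes and between 16 and 18 dpp at 3774, and at 0 in each earlier step. Without the library labelled WT replicate 2 at 16 dpp the 4 steps gave 0, 193, 1669 and 1005. The X-linked minus autosomal effect changed by 0.07, 0.23, 0.24 and 0.61 over these steps (camera p = 9.41e-04 to 5.00e-22, and 0.535 to 0.0768 as p with an estimated correlation), and by 0.07, 0.23, 0.42 and 0.42 without the library labelled WT replicate 2 at 16 dpp (0.356, 0.0931, 0.033 and 0.0628 as p with an estimated correlation). From 10 to 12 dpp list medians changed by 0.36 for meiotic entry, 0.26 for recombination, 0.33 for the axis, 0.12 for the silencing response, 0.09 for X-linked and 0.18 for Y-linked genes, 0.28 for Leydig cells and 0.32 each for endothelial cells and macrophages. From 12 to 14 dpp they changed by 0.18 for spermatogonia, −2 for pachytene, −0.49 for the piRNA pathway, 0.24 for X-linked and 0.37 for Y-linked genes, −0.62 for retrogenes, 0.26 for p53 targets and 0.16 for Sertoli cells. From 14 to 16 dpp the changes were −0.78 for pachytene, −0.37 for the piRNA pathway, 0.19 for X-linked genes, 0.17 for p53 targets, 0.29 for interferon response, 0.31 for Sertoli cells and 0.36 each for Leydig cells, myoid cells and macrophages. From 16 to 18 dpp they were 0.38 for spermatogonia, 0.55 for meiotic entry, −0.6 for pachytene, −0.38 for the piRNA pathway, 0.72 for X-linked and 0.98 for Y-linked genes, −0.46 for retrogenes and 0.49 for Sertoli cells. These list changes passed with camera at its preset correlation and none of them passed with an estimated correlation. Without the library labelled WT replicate 2 at 16 dpp, 6 no longer passed with camera. They were Leydig cells from 10 to 12 dpp (0.27), myoid cells from 14 to 16 dpp (0.24), and meiotic entry (0.3), pachytene (−0.19), the piRNA pathway (−0.21) and retrogenes (−0.27) from 16 to 18 dpp. From 14 to 16 dpp meiotic entry (0.3), Y-linked genes (0.63) and retrogenes (−0.48) passed instead, and pachytene changed by −1.13 and X-linked genes by 0.44. From 16 to 18 dpp the changes were 0.46 for X-linked and 0.45 for Y-linked genes.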

How the results depend on the processing

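The alternatives that left the library labelled WT replicate 2 at 16 dpp out of the WT change or of the shared WT fit were chosen after seeing the data, and the others before. Of 430 alternative values of the main results 322 kept their direction and their side of the threshold, or a count within 1.5 times, and 108 did not, and for these the cause was not tested. All alternatives fixed before the data were examined were run. For changed genes at 10 dpp (4) DESeq2's Wald test gave 252, limma-voom 196, TPM 0, no filter on low counts 870, the replicate block 293, replicates 1 and 2 against 3 and 4 as a covariate 486, a fit of all 40 libraries 0 and an adjusted p under 0.01 0. At 12 dpp (20) the same settings without limma-voom gave 55, 6, 171, 87, 59, 0 and 13, and at 14 dpp (387) 1189, 86, 27, 1615, 1, 1542 and 0. At 16 dpp (3854) limma-voom gave 10088, the covariate 2425, all 40 libraries 8629, both libraries with the same animal number left out 7258 and an adjusted p under 0.01 0. For piRNA loci the replicate block gave 27 at 10 dpp (11) and 52 at 16 dpp (88), an adjusted p under 0.01 gave 0 at 10 dpp, no filter 66 at 12 dpp (43), and both libraries left out 1.6e+02 at 16 dpp. X-linked genes at 10 dpp, at −0.02, passed on log2(TPM + 1) at −0.02. For the relation with WT change Spearman's rho was −0.14 at 12 dpp, −0.692 at 14 dpp and −0.801 at 18 dpp, and r at 18 dpp was −0.905 without the doubted library in the WT change. In WT, 10 to 12 dpp (6) gave 0 at an adjusted p under 0.01, 1716 in a fit of the 8 libraries of those ages, 1.4e+02 with DESeq2's Wald test and 10 without the doubted library. The step from 12 to 14 dpp (931) gave 3 at an adjusted p under 0.01, 10 with no filter, 4 with the replicate block, 1857 with the Wald test and 1953 without the doubted library. The step from 14 to 16 dpp (0) gave 36 with the Wald test, and 16 to 18 dpp (8324) gave 2588 at an adjusted p under 0.01 and 0 in a fit of its 8 libraries. Gene lists past the threshold (44) numbered 0 with an estimated correlation and 20 with fry. Hbb-bs and Hba-a1 at 16 dpp reversed, from −0.10 and −0.04 to 0.62 and 0.58 with limma-voom, and Hba-a1 ranged from −0.19 to 0.50 with single libraries left out, with 0.50 without WT replicate 2.

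With single libraries left out, changed genes ranged from 0 to 656 at 10 dpp, 10 to 106 at 12 dpp, 0 to 1076 at 14 dpp, 0 to 8806 at 16 dpp and 11072 to 13777 at 18 dpp. The X-linked minus autosomal difference ranged from −0.03 to −0.02, 0.03 to 0.05, 0.16 to 0.28, 0.35 to 0.59 and 0.91 to 1.21 at the 5 ages, and r from −0.276 to −0.178 (−0.178 without KO replicate 2 and −0.179 without WT replicate 4), −0.532 to −0.314, −0.893 to −0.809, −0.84 to −0.788 and −0.865 to −0.851. At 10 dpp X-linked genes passed at −0.03 without WT replicate 4 or KO replicate 4. The piRNA loci ranged from 0 to 27 at 10 dpp (27 without WT replicate 1, 18 without KO replicate 4, 2 without KO replicate 2, 1 without KO replicate 1 and 0 without KO replicate 3, WT replicate 3 or WT replicate 4), 36 to 61 at 12 dpp, 85 to 116 at 14 dpp, 73 to 166 at 16 dpp (166 without WT replicate 2) and 178 to 186 at 18 dpp. The difference among ages ranged from 8883 to 11240 genes, the lists past the threshold from 40 to 48, and the WT steps from 0 to 12, 1 to 2119, 0 to 4965 and 3374 to 10475 genes. Pairing by replicate number was not established at 10 dpp (r = −0.0659, 0.0787, −0.0362 and 0.0036 for numbers 1 to 4), 16 dpp (0.358, −0.0236, 0.0929 and −0.027) or 18 dpp (0.0443, 0.183, 0.0398 and 0.231). Depth was not varied on its own, and the simulated counts held no variation shared across genes. In simulated counts 1.5-fold changes were recovered at 79.1% and 73.1% at 10 and 12 dpp, where the biological coefficient of variation was 0.0684 and 0.0713, and at 8.96% to 17.9% at the later ages, where it was 0.202 to 0.243, at 9219910 to 14949514 counts per library over all ages.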

Other observations

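At 292 of 14615 genes every Setx-KO library of 18 dpp lay above all 20 WT libraries of any age. Spon2, a secreted matrix protein gene, was at 8.75 CPM or more in these libraries against at most 7.53 in WT, the cell cycle inhibitor Cdkn1c at 27.6 or more against at most 22.3, and Cyp4f17 at 11.4 or more against at most 10.3. Of the gene lists, 4 of 18 p53 targets, 3 of 10 endothelial genes, 2 of 13 macrophage genes and 1 each of the spermatogonial, Sertoli and X-linked genes were among the 292. Against the 19 WT libraries other than the one labelled WT replicate 2 at 16 dpp, Ccnb3 was at 227 CPM or more against at most 64, Zfy2 at 56.4 or more against at most 16.4, the X-linked Tex13c2 at 63.3 or more against at most 17.7 and Foxd2, a forkhead factor gene, at 4.97 or more against at most 1.39. The genes named here were chosen after their values were seen.

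At 18 dpp 63.4% of 481 tested lincRNA genes fell and 16.6% rose, 47.9% of 599 antisense genes fell and 21.9% rose, and of 14644 protein-coding genes 34.1% fell and 40.2% rose. At 14 dpp 10.8% of 305 lincRNA genes fell and 0.328% rose, and 1.91% of 14278 protein-coding genes fell and 0.273% rose. At 16 dpp without the library labelled WT replicate 2, 53.2% of 459 lincRNA genes fell and 6.1% rose, and 27.8% of 14608 protein-coding genes fell and 25.8% rose. The difference between these classes was not tested.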
